A study of Mus musculus with 4 samples.

How the data were processed

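Total RNA was taken from 4 mouse bone marrow cultures: macrophages and osteoclasts of wild-type mice, and macrophages and osteoclasts of LysM-St18flox mice. Per the labels, the cells grew in RPMI medium with 10% serum, RNA was extracted with TRIzol, and 100 ng of it was labelled with Cy3 in the Quick Amp procedure. Each group had 1 array. Whether the cell types of a genotype came from the same mouse, and the sex and number of mice, are not given in the sources used here. Samples were grouped by the cell type and genotype in the labels.

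The arrays were scanned and read with Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes. The deposited scanner files give, per the file headers, a processed intensity for each spot, which is the signal after background subtraction and spatial detrending within the array, with no scaling between arrays. They also give the median intensity of the spot and of its local background in pixels, per the file headers, and flags of other kinds, deposited as 0 or 1, for spots well above background, saturated or uneven. The authors also deposited a table of log2 values for 30909 probes. How the authors made this table is not given in the sources used here, but from the values its columns are quantile-normalized, since sorted columns differ by at most 0.001. The table holds levels and not ratios, it is not centred on 0, and every column has a median of 9.39. All 30909 probes matched a scanner probe, 30893 of them were well above background on all 4 arrays, and each column had a correlation of at least 0.9996 with the array it belongs to.

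Each array had 59305 spots for 56605 probes besides 3671 control spots. Spots well above background numbered 36467 in wild-type macrophages, 34980 in wild-type osteoclasts, 37509 in LysM-St18flox macrophages and 36615 in LysM-St18flox osteoclasts, and 126, 80, 93 and 107 spots called uneven or outlying were left out. The 75th percentile of the signal was 635.5, 769.9, 1159.3 and 1061.9 in the same order, and the slope of the spike-in controls 0.970, 0.981, 0.957 and 0.992. Of 300 probes with 10 spots each, 283, 283, 285 and 286 were well above background in all their spots, and the SD between the spots of these was 0.042, 0.036, 0.033 and 0.031 (median, log2). This is the precision of the measurement within an array and not the spread between cultures.

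The values analysed were log2 of the processed signal, averaged over the spots of a probe, minus the 75th percentile of the array. Probes were named through their RefSeq accession and a table of mouse genes of assembly GRCm38.p6, which was used only for names and for which genes neighbour each other. No coordinates are given, because the file headers name another genome build. Of the probes, 35886 had a RefSeq accession and 32994 (58.3%) were named, for 22911 genes, and 23611 probes were left unnamed. A gene was represented by its probe with the highest mean signal, and 7899 genes had more than 1 probe.

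A gene entered a comparison when it was well above background on at least 1 of the 2 arrays, and was counted as changed when the difference was at least 2-fold. Where only 1 array was well above background, the difference was taken against the lowest signal well above background or the dim signal itself, whichever was higher, and is a bound. No test was made and no p-value computed, since no group had a second array. The response to RANKL was compared between genotypes by the correlation and the total least squares slope across genes, and by genes selected on the mean of both responses. The genotype difference was compared between cell types by the number of genes changed in both, against the number for independent lists.

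Gene lists were set before the data were examined, as were the comparisons, the settings and their alternatives, except where stated. There were 29 lists: resorption genes, osteoclast regulators and fusion genes, V-ATPase subunits, respiratory chain, TCA cycle with PGC1 coactivators, glycolysis, macrophage surface and regulator genes, alternative activation, inflammatory cytokines and chemokines, type I interferon response, antigen presentation, angiogenic factors and receptors, hypoxia, cell cycle, lysosome, cholesterol synthesis, stress and immediate early genes, markers of 9 other cell types (neutrophils, B cells, T and NK cells, erythroid cells, mast cells and basophils, stroma, endothelium, dendritic cells and megakaryocytes), sex-linked genes, neighbours of St18, and the lysozyme locus. Each list's median difference, with values below a common floor of -4.89 set to it, was placed among 10000 random lists of the same size drawn within 20 bins of expression. A list was called apart from random lists below the percentile 2.5 or above 97.5. At least 4 measured members were needed, so sex-linked genes and the lysozyme locus are given by gene. Of the 108 pairs of list and comparison, 5.4 are outside these limits by chance. The percentile describes these arrays and is no test.

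Named genes followed a rule. They were St18, Lyz2 and Vegfa, the 10 highest and 10 lowest of osteoclast against macrophage (by the smaller difference of both genotypes), the 8 highest and 8 lowest of LysM-St18flox against wild-type (by the smaller difference of both cell types), the 5 highest and 5 lowest within each cell type, and the 5 highest and 5 lowest differences between the responses. Ranked genes had to be well above background on every array ranked and, on the brightest of these arrays, brighter than the median detected gene. On the other arrays they could lie near the lowest signal well above background. Members of the lists were named as examples, those with the largest or smallest differences by the rule, and others for their known function, which were chosen after their values were seen.

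Alternatives tried were quantile normalization, cyclic loess, a median shift, normexp background correction with an offset of 50, the authors' values, well above background on both arrays, no filter on dim probes, the median over all probes of a gene, and thresholds of 1.5-fold and 3-fold. Normexp was planned on the mean spot signal, which the files used do not hold, and used the median spot signal instead. Chosen after seeing the data were a count of genes whose probes all go the same way, results without histone genes and structural RNAs, and lists without Vegfa. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

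The procedure was tested on simulated data. For the gene calls and the slope, each simulated array was the wild-type macrophage array with noise about as small as the spread between spots. Changed genes were drawn from those brighter than the array's 75th percentile. No variation between mice or cultures was simulated, so these calls check the procedure and give no error rate for the real arrays. For osteoclast against macrophage in the wild type over 22903 genes, 63 of 63 genes changed 3-fold and 76 of 76 genes changed 4-fold were called, 0 of 61 genes changed 1.5-fold and 0 of 14449 unchanged genes were called, and the direction was right for 139 of 139. For LysM-St18flox against wild-type macrophages with no change simulated, 0 of 14649 genes were called. A simulated slope of 1.5 between the responses was found as 1.51. For LysM-St18flox against wild-type osteoclasts over 13671 genes, 10 of 200 random lists were called apart, and 18 of 20 lists moved by 0.5 were called higher.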

Results

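Gene expression was measured in cells grown from mouse bone marrow, on 4 one-colour microarrays, with 1 array for each of 4 groups. Macrophages were obtained by keeping marrow cells for 4 days in 25 ng/ml M-CSF, the growth factor of the macrophage lineage. Osteoclasts, the multinucleated cells that resorb bone, were obtained from such macrophages by 3 further days in 25 ng/ml M-CSF with 50 ng/ml RANKL, the cytokine that drives osteoclast formation. RANKL and time in culture therefore changed together between the cell types. Each cell type was prepared from wild-type mice and from mice called LysM-St18flox, a name that by convention denotes a loxP-flanked St18 gene together with Cre recombinase expressed from the lysozyme M locus. St18 encodes a zinc finger transcription factor. The comparisons asked how osteoclasts differ from macrophages in each genotype, and how LysM-St18flox cells differ from wild-type cells in each cell type.

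The share of probe spots well above background was 61.5% on the wild-type macrophage array, 59.0% on the wild-type osteoclast array, 63.2% on the LysM-St18flox macrophage array and 61.7% on the LysM-St18flox osteoclast array, and no spot was saturated. Of 22903 genes with a named probe, 15831 were well above background on at least 1 array and 13671 on all 4. With 1 array per group, no difference given here has a replicate check, and the number of arrays limits the precision. A gene was counted as changed when its 2 arrays differed by at least 2-fold, a criterion of size and not a test. Spots of the same probe varied little within an array. From these median SDs, that of a difference between 2 arrays was calculated as 0.045 to 0.055 on the log2 scale. This was not measured between arrays, and it leaves out the variation between arrays, mice and cultures. Differences are on the log2 scale unless a fold is given.

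St18, the targeted gene, was well above background on all 4 arrays with its brighter probe. Its normalised log2 signal was 0.30 in wild-type macrophages and -1.52 in LysM-St18flox macrophages, a 3.51-fold lower level. In osteoclasts it was 1.55 in the wild type and 1.12 in LysM-St18flox, a 1.35-fold lower level that did not reach 2-fold. St18 was also 2.39-fold higher in wild-type osteoclasts than in wild-type macrophages and 6.23-fold higher in LysM-St18flox osteoclasts than in LysM-St18flox macrophages. A second, much dimmer St18 probe was well above background in LysM-St18flox osteoclasts alone, with a log2 signal of -4.60. Its difference between genotypes went the other way, at 0.70 in macrophages and 1.06 in osteoclasts, with the remaining signals not well above background. With the median over both probes in place of the brighter probe, the difference between macrophages was -0.55. Where the probes lie relative to the floxed part of the gene is not given in the sources used here, so the St18 signal does not check the deletion. Lyz2, the gene whose promoter drives the Cre, was well above background on all arrays, and its difference between genotypes was -0.07 in macrophages and -1.05 in osteoclasts.

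**Figure D1:**
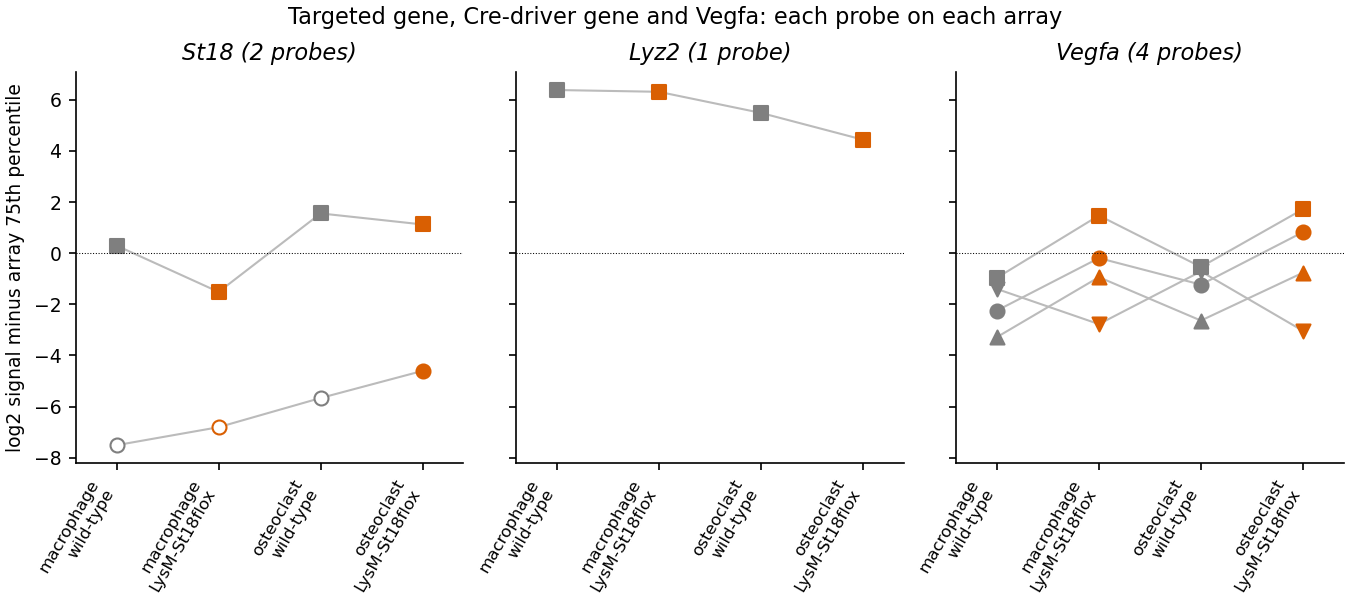
Normalised log2 signal (signal minus the array's 75th percentile) of every probe of St18, Lyz2 and Vegfa on the 4 arrays, with wild-type in grey and LysM-St18flox in orange. Each symbol shape is a probe, grey lines join the values of the same probe, and open symbols are not well above background. The brighter St18 probe fell from 0.30 to -1.52 between the macrophage arrays, and 3 of the 4 Vegfa probes were higher in LysM-St18flox in both cell types.

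Osteoclasts of both genotypes expressed the bone resorption program at levels far above macrophages. Ctsk, the main collagen-degrading protease of the osteoclast, was 207-fold higher than in macrophages in the wild type and 325-fold higher in LysM-St18flox. Acp5, the tartrate-resistant acid phosphatase used as an osteoclast stain, was 61.1-fold and 67.2-fold higher. Mmp9, a gelatinase, was not well above background in wild-type macrophages, and its difference was at least 10.18 in the wild type, and a measured 11.85 in LysM-St18flox. Macrophage genes fell in the same comparisons. Fcrls, an Fc receptor-like gene of resident macrophages, was at -5.67 in the wild type and -7.80 in LysM-St18flox, Siglec1, a sialic acid receptor of macrophages, at -5.10 and -5.61, and Fcgr1, the high-affinity IgG receptor, at -4.30 and -4.39.

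In the wild type, 840 genes were at least 2-fold higher and 1078 at least 2-fold lower in osteoclasts, which is 13% of 14734 genes measured on at least 1 of the 2 arrays. In LysM-St18flox, 1702 genes were higher and 1905 lower, 23.2% of 15576, and with each array centred on its median the split was 2204 higher and 1522 lower. Without the filter on dim probes the wild-type total rose from 1918 to 2985 genes. Both genotypes shared 1605 of these genes with the same direction, against 219.1 for independent lists, and 8 genes changed in opposite directions. Among genes ranked by the smaller of the 2 differences, the highest after Ctsk were Spns2, a sphingosine-1-phosphate transporter (6.49 in the wild type and 8.73 in LysM-St18flox), Akr1c18, a steroid dehydrogenase (6.43 and 8.01), and Cyp2s1, a cytochrome P450 (78.4-fold and 511-fold). Acp5 (5.93 and 6.07), Plxna4, a semaphorin receptor (5.89 and 7.16), Chpf, which polymerises chondroitin (5.84 and 6.80), the serine protease Htra1 (6.06 and 5.84), Kbtbd11 (5.82 and 6.82) and Dcstamp, needed for cell fusion (5.82 and 8.80), followed. The lowest besides Fcrls, Siglec1 and Fcgr1, given above, were F13a1, the coagulation factor XIII A chain (-4.59 and -5.26), Cbr2, a carbonyl reductase (-4.56 and -5.75), Saa3, an acute-phase protein (-4.33 and -4.93), Ctla2b (-4.24 and -5.21), Ctla2a (-4.15 and -4.67), Iigp1, an interferon-inducible GTPase (-4.24 and -4.12), and Hpgd, which degrades prostaglandins (-4.09 and -5.71). Iigp1 in wild-type osteoclasts (-4.595) lay near the lowest signal well above background on that array (-4.892). So did Spns2 in LysM-St18flox macrophages (-4.933 against -5.565). The sizes of these differences are therefore uncertain.

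Of 13 resorption genes, 8 rose at least 2-fold in wild-type osteoclasts and 12 in LysM-St18flox osteoclasts, and none fell. Their median difference was 4.20 and 5.56, above all 10000 random lists of the same size and expression in each case. Src was at 4.20 and 5.56, Atp6v0d2, the osteoclast-rich subunit of the proton pump, at 5.54 and 6.38, and Itgb3, the beta3 integrin, at 2.86 and 3.80. Slc4a2, the anion exchanger that balances acid secretion, was at 0.57 in the wild type and 2.01 in LysM-St18flox. Of 17 regulators and fusion genes, 11 rose in each genotype and 2 fell, with medians of 1.73 and 1.53. Nfatc1, the master transcription factor of osteoclasts, was at 2.33 and 3.33, Oscar at 4.34 and 6.19, and Ocstamp at 5.33 and 7.51. The members that fell were Trem2 (-1.07 and -1.42) and Fcer1g (-1.07 and -1.03).

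Genes of energy metabolism and proton transport were higher as groups in osteoclasts. The 23 measured respiratory chain subunits had a median difference of 0.53 in the wild type, where 1 rose 2-fold, and 1.06 in LysM-St18flox, where 14 did. The 15 genes of the TCA cycle with the PGC1 coactivators had medians of 0.54 and 1.26, with 2 and 13 members past 2-fold. Ppargc1b, the coactivator of mitochondrial biogenesis in osteoclasts, was at 3.06 and 4.13, Idh3a at 1.04 and 2.40, and Cyc1 at 0.92 and 2.20. The 15 subunits of the V-ATPase, the proton pump that acidifies the resorption space, had medians of 0.42 and 1.03, and Atp6v0a1 was the member that fell (-1.51 and -2.16). The percentiles of these 6 medians among the random lists ran from 99.92 to 100. The glycolysis list stayed within the random lists at -0.06 and 0.44.

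Macrophage, inflammatory, interferon and sterol groups were lower in osteoclasts of both genotypes. Of 19 macrophage surface and regulator genes, 9 fell in the wild type, and in LysM-St18flox 13 fell and 1 rose, with medians of -0.99 and -1.63. Irf8, a transcription factor that restrains osteoclast formation, was at -2.55 and -3.58, Maf at -3.22 and -4.28, and Marco, a scavenger receptor, at -3.78 and -4.84. Of 19 type I interferon genes, 15 fell in each genotype, with medians of -1.89 and -1.59. Ifit3 was at -2.90 and -2.53 and Oasl2 at -2.63 and -2.52, while the chemokine gene Cxcl10 was at -0.44 in the wild type and 1.28 in LysM-St18flox. The 16 inflammatory genes had medians of -1.17 and -1.62, with Ccl4 at -2.66 and -3.16 and Cxcl2 at -1.96 and -2.34, against the interleukin-1 receptor antagonist gene Il1rn at 3.00 and 3.36. The 11 genes of alternative activation had medians of -1.04 and -1.81 (the latter -0.80 without the filter on dim probes), with Mrc1, the mannose receptor, at -3.20 and -4.69. The 18 cholesterol synthesis genes had medians of -0.83 and -0.78, with Cyp51 at -1.66 and -1.23. These 10 medians lay below all random lists. The 20 lysosome genes lay slightly lower, at -0.28 and -0.25 (percentiles 0.43 and 0.26). None passed 2-fold in the wild type, and in LysM-St18flox 3 fell and 1 rose, with 13 of the 20 below 0 and 7 above.

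The 13 measured antigen presentation genes had a median of 0.31 in wild-type osteoclasts (percentile 98.57) and -0.67 in LysM-St18flox osteoclasts (percentile 0.06) against macrophages of the same genotype, and this difference between genotypes was not tested. In the wild type 7 members lay above 0 and 6 below, with 1 past 2-fold, H2-DMa (-1.23 and -1.49), and in LysM-St18flox 12 lay below 0, with Cd86, a costimulatory receptor (0.71 and -1.04), also past 2-fold. The wild-type value moved inside the random lists with the normexp background correction (percentile 86.66) and with no filter on dim probes (50.86). The cell cycle list was within the random lists in both genotypes (-0.02 and 0.23), as were the angiogenic list (-0.05 and 0.17), the hypoxia list (-0.12 and 0.07) and the stress and immediate early list (0.13 and 0.07). Within the angiogenic list Vegfc (4.64 and 5.09) and Pgf (4.61 and 4.59) rose, and Plau (-2.17 and -2.04) and Nrp1, a VEGF co-receptor (-2.31 and -3.43), fell.

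Markers of other marrow cells were also set against the random lists. Neutrophil markers were lower in osteoclasts, at -0.34 in the wild type (percentile 0.57, and -0.60 with the authors' values) and -0.86 in LysM-St18flox (0.01), with Mmp8 at -2.08 and -3.46 and S100a9 at -0.33 and -1.16. B cell markers had medians of -0.55 (0.74) and -0.44 (8.0) over 7 measured genes. The wild-type call was lost under 4 of 8 alternative settings. Markers of T and NK cells (-0.23 and -0.24), erythroid cells (-0.25 and -0.33), mast cells and basophils (0.05 and 0.16), stromal cells (0.08 and 0.00), endothelium (-0.03 and -0.22), dendritic cells (0.00 and 0.00) and megakaryocytes (0.07 and -0.54) stayed within the random lists. Among them Pf4, a platelet chemokine also made by macrophages, was at -3.02 and -3.84, and Cd5 was at 3.80 and 5.90. The 20 measured neighbours of St18 on its chromosome had medians of -0.03 and -0.04.

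Most genes that responded to RANKL did so in the same direction in both genotypes, and most responded more strongly on the LysM-St18flox arrays. Time in culture changed together with RANKL, so its effect is part of this response. Dcstamp rose by 5.82 in the wild type and by 8.80 in LysM-St18flox, and Scin, an actin-severing protein, by 5.21 and 8.63. Serpine2, a protease inhibitor, was at 0.90 in the wild type and 4.99 in LysM-St18flox. Akap6, a kinase-anchoring protein, rose by 5.09 and 8.95, Rgs16, a G protein regulator, by 3.86 and 7.11, and Pip5k1b, a phosphoinositide kinase, by 3.09 and 6.11. In LysM-St18flox macrophages, Akap6 (-5.04) and Rgs16 (-5.15) lay near the lowest signal well above background on that array (-5.565). The sizes of their responses are therefore uncertain. At the other end, Gpr162 was at -0.17 in the wild type and -3.68 in LysM-St18flox, Nxpe5 at -2.95 and -5.66, Spic, a transcription factor of red pulp macrophages, at 4.04 and 1.44, Fcgr2b, the inhibitory IgG receptor, at 1.28 and -1.27, and Aoah, which deacylates lipopolysaccharide, at -1.15 and -3.51.

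Across the 13671 genes well above background on all 4 arrays, the 2 responses had a correlation of 0.865, and the total least squares slope of the LysM-St18flox response on the wild-type response was 1.51. Genes are not independent replicates, so this slope describes the 4 arrays. Of 2082 genes with a mean response of at least 2-fold, 1809 (86.9%) responded more strongly in LysM-St18flox and 273 in the wild type, with a median excess in LysM-St18flox of 0.65. The difference lay in both cell types. The 870 genes that were higher in osteoclasts were lower in LysM-St18flox than in wild-type macrophages (median -0.34) and higher in LysM-St18flox than in wild-type osteoclasts (median 0.39). The 1212 genes that were lower in osteoclasts had medians of 0.32 and -0.29. With each array centred on its median the last of these was -0.06, so for genes lower in osteoclasts the osteoclast side depended on the scaling. The 2 responses differed by at least 2-fold for 1080 genes, 438 with the higher difference in LysM-St18flox and 642 with the lower.

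**Figure D2:**
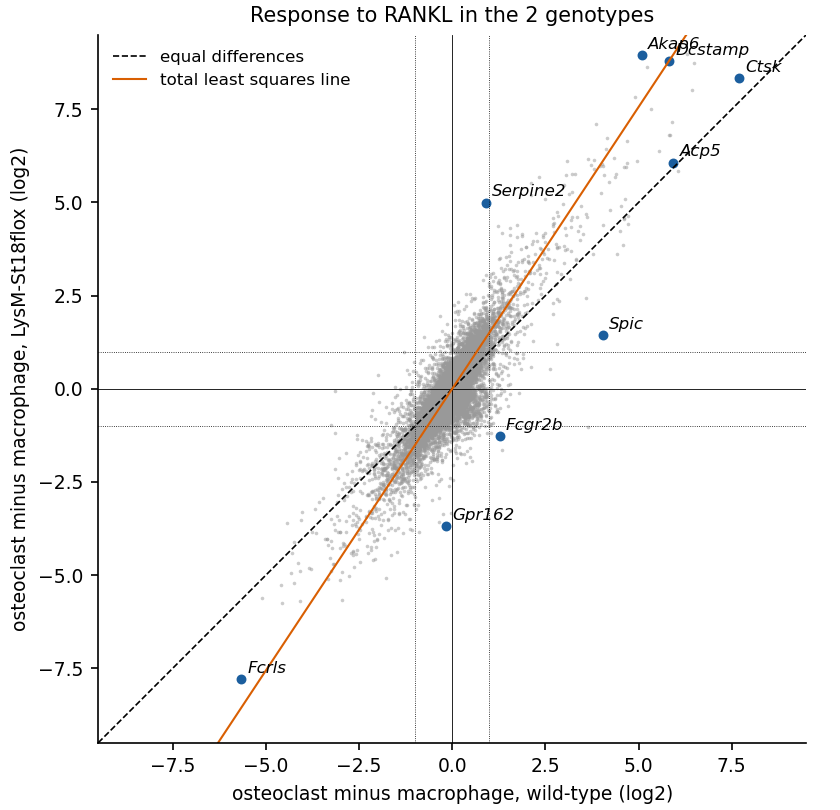
Osteoclast minus macrophage difference (log2) in the wild type on the horizontal axis and in LysM-St18flox on the vertical axis, for the 13671 genes well above background on all 4 arrays (grey points). Dotted lines mark 2-fold, the dashed line equal differences, and the orange line the total least squares slope of 1.51. Most points far from 0 lie on the steep side of the dashed line, and named genes such as Serpine2 and Spic lie away from the orange line.

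In macrophages, LysM-St18flox cells had higher levels of F13a1, Vegfa and antigen presentation genes and lower levels of cell cycle genes. F13a1 was 9.50-fold higher than in the wild type. Vegfa, the main angiogenic growth factor, was 5.41-fold higher with its brightest probe, higher with 2 further probes and 2.59-fold lower with another. Cd74, the invariant chain of MHC class II, was higher by 1.44 and Cd86 by 1.53. All 24 cell cycle genes lay below 0, with a median of -0.70, below all random lists, although only Tyms passed 2-fold (-1.08).

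A total of 500 genes were at least 2-fold higher and 452 at least 2-fold lower in LysM-St18flox macrophages, 6.3% of 15161. This total of 952 was 557 with the normexp background correction and 2093 without the filter on dim probes. Among the genes bright enough to be ranked, the highest after F13a1 were the orphan receptor gene Gpr162 (3.24), Fxyd2, a modulator of the sodium pump (3.12), and Pltp, a phospholipid transfer protein (2.67). The lowest ranked genes were Cd207, the lectin langerin (-2.72), the adhesion receptor gene Adgrg3 (-2.64), the small nucleolar RNA Snora81 (-2.41), Fabp7, a fatty acid binding protein (-2.29), and Notch4 (-2.24). Of the 13 antigen presentation genes 5 rose and none fell, with a median of 0.56 above all random lists. They were H2-Ab1 (1.01), H2-Eb1 (1.22), Cd74, Cd86 and Ciita, the class II transactivator (2.47-fold). The type I interferon list had a median of 0.53, also above all random lists, and its members past 2-fold were Ifit1 (1.06) and Ifi44 (1.32). Among genes of alternative activation Mrc1 (1.41), Clec10a (1.49) and the chemokine gene Ccl24 (2.57) rose, with a list median of 0.13 within the random lists.

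Of the angiogenic list, Vegfa, Thbs1, which encodes thrombospondin (2.25), Pdgfc (1.80) and Adm (a bound of 1.16) rose, and Pdgfa (-1.31), Flt1, a VEGF receptor (-1.29), and Plaur (-1.04) fell, with a median of -0.27 (percentile 1.80) that was lost under 3 of 9 settings. The hypoxia list had a median of 0.30 (percentile 99.60), and Vegfa, Egln3 (1.39), Ankrd37 (1.05), Ddit4 (2.01-fold) and, by its bound, Adm passed 2-fold. Without Vegfa, a choice made after seeing the data, its median was 0.11 (percentile 86.84), and 4 other settings also ended this call. The V-ATPase median of 0.06 was above random lists (percentile 99.39), and it moved inside the random lists with quantile normalization (96.68) and the authors' values (96.79). Resorption genes (0.00), regulators and fusion genes (0.00), respiratory chain (-0.33), TCA cycle (-0.15), glycolysis (-0.31), macrophage (-0.03), inflammatory (-0.14), lysosome (-0.08), cholesterol (0.14) and stress genes (0.03) stayed within the random lists. Members of these lists still differed singly: Dcstamp (-1.81), Ocstamp (-1.01), Cx3cr1, the fractalkine receptor (-1.62), the prostaglandin synthase gene Ptgs2 (-2.15) and Ccl2 (-1.30) fell, and Mertk, a receptor for dying cells (1.66), Prdm1 (1.32) and Egr1 (3.34) rose.

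Markers of neutrophils were higher in LysM-St18flox than in wild-type macrophages as a list (median 0.30, percentile 99.40, and 0.14 with normexp), with Camp at 0.77 and Lcn2 at 0.81 and no member past 2-fold. Megakaryocyte markers had a median of 0.55 (99.57) and endothelial markers -0.65 (0.24), each over 6 or fewer genes, and both calls were lost with no filter on dim probes. The lists for B cells (-0.22), T and NK cells (-0.05), erythroid cells (0.10), mast cells and basophils (0.00), stroma (0.00) and dendritic cells (0.00) stayed within the random lists. Xist, the transcript that silences an X chromosome, was well above background on all arrays and differed by -0.58, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were not well above background on any array. The neighbours of St18 had a median of 0.08, and none of these 20 genes changed 2-fold.

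In osteoclasts, LysM-St18flox cells had higher levels of resorption, fusion and interferon genes and of Vegfa, and lower median levels of the macrophage and cell cycle lists. Mmp9 was higher by 2.08, Car2, the carbonic anhydrase that supplies acid, by 2.26, Oscar by 2.30 and the calcitonin receptor gene Calcr by 2.10. Vegfa was 4.78-fold higher with its brightest probe, higher with 2 further probes and 5.01-fold lower with another. Acp5 and Ctsk differed by less than 2-fold, at -0.29 and 0.29.

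A total of 556 genes were at least 2-fold higher and 576 at least 2-fold lower in LysM-St18flox osteoclasts, 7.7% of 14614. With each array centred on its median instead, the split was 996 higher and 316 lower, and the median of all genes moved from -0.01 to 0.24. The total of 1132 was 537 with the normexp background correction, 695 with the authors' values and 2330 without the filter on dim probes. Among the genes bright enough to be ranked, the highest were Scd2, a fatty acid desaturase (3.66), Kbtbd11 (3.14), Serpind1, heparin cofactor II (2.63), Mt3, a metallothionein (2.52), and Klra17, a lectin-like receptor (2.47). The lowest ranked genes were Gsta3, a glutathione transferase (-2.30), the large ribosomal RNA Rn28s1 (-1.95), the membrane protein gene Ms4a7 (-1.82), Treml4 (-1.69) and Dcaf12l2 (-1.65).

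Of the 13 resorption genes, 8 rose and none fell, with a median of 1.24, and Mmp14 (1.80), Atp6v0d2 (1.77), Slc4a2 (1.36) and Src (2.46-fold) were among them. Of 17 regulators and fusion genes, 6 rose and none fell, with a median of 0.81, led by Siglec15 (2.34), Oscar and Calcr, with Nfatc1 at 1.01 and Dcstamp at 1.18. V-ATPase subunits had a median of 0.70 with no member past 2-fold, the TCA cycle list 0.48 with Ppargc1b (1.52) past 2-fold, and the respiratory chain 0.36 with none. The interferon list had a median of 0.83 and 8 members that rose, among them Rsad2 (1.81), Ifi44 (1.74), Ifit1 (1.72) and Cmpk2 (1.47). These 6 medians lay above all random lists. With each array centred on its median the TCA cycle list was at 0.73 and the respiratory chain at 0.61, and with the authors' values the regulators and fusion genes were at 0.36. Macrophage genes had a median of -0.44 and cell cycle genes of -0.46, both below all random lists. Of the 19 macrophage genes 15 lay below 0 and 1 passed 2-fold. No cell cycle gene passed 2-fold, with Tyms lowest at -0.75, and 24 of 24 lay below 0, or 21 with each array centred on its median and 22 with normexp. Centring on the median brought these list medians to -0.19 for macrophage genes and -0.21 for cell cycle genes, still below all random lists.

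The hypoxia list had a median of 0.47 (percentile 99.98) and 5 members past 2-fold, among them Egln3 (2.07), Ankrd37 (1.57) and Adm, for which the bound was 2.28. The list stayed above the random lists without Vegfa (0.47, percentile 99.97). The angiogenic list had a median of -0.46 (percentile 0.00), or -0.21 with each array centred on its median (percentile 0.01), while Vegfa, Vegfb (1.22), Hbegf (1.49) and Adm rose and Hgf fell, with a bound of -1.69. Cholesterol synthesis genes had a median of 0.33 (99.79) with no member past 2-fold. Glycolysis (0.14), alternative activation (0.00), inflammatory (-0.20), antigen presentation (0.14), lysosome (-0.08) and stress genes (0.03) stayed within the random lists, and in them the lipase gene Lipa (-1.46), Hmox1, a heme oxygenase (-1.58), Ccl3 (-1.04) and Il12a (-1.19) fell and Ccl24 (1.03) rose.

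Neutrophil markers had a median of -0.23 (percentile 3.09) in osteoclasts. B cell markers were at -0.55 (0.94) and stromal markers at -0.45 (1.52), each over 7 genes, and these calls were lost under 3 and 6 of 8 settings. The lists for T and NK cells (0.00), erythroid cells (0.05), mast cells and basophils (0.10), endothelium (0.00), dendritic cells (0.00) and megakaryocytes (-0.20) stayed within the random lists, although the platelet chemokine gene Ppbp was at -2.33. Xist differed by -0.46, and the neighbours of St18 had a median of 0.08.

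**Figure D3:**
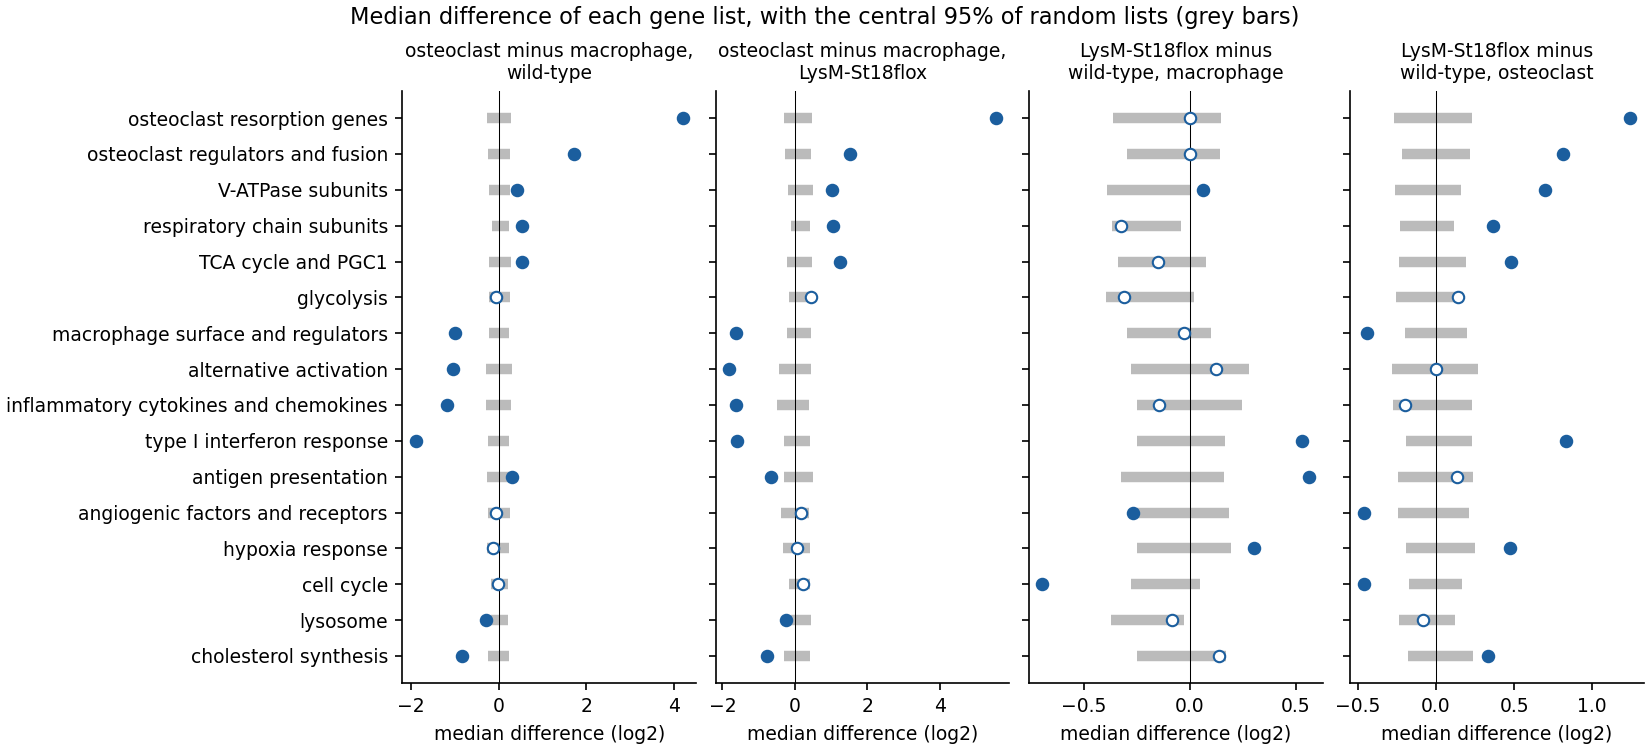
Median log2 difference of each of 16 gene lists in the 4 comparisons, with 1 panel per comparison and its own horizontal scale. Filled points lie outside the central 95% of 10000 random lists matched on size and expression (grey bars), and open points lie inside it. The resorption list was at 4.20 and 5.56 in osteoclasts against macrophages, and at 0.00 and 1.24 in LysM-St18flox against wild-type macrophages and osteoclasts.

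The genotype difference was partly shared by the 2 cell types, which had no array in common. F13a1 was higher by 3.25 in macrophages and 2.57 in osteoclasts, Vegfa by 2.44 and 2.26, and Kbtbd11 by 2.14 and 3.14. The structural RNAs Rn28s1 (-2.13 and -1.95) and Snora81 (-2.41 and -1.51) and the histone H4 genes H4c11 (-1.47 and -1.48), H4c3 (-1.38 and -1.41), H4f16 (-1.36 and -1.37) and H4c4 (-1.30 and -1.29) were lower. Histone H4 genes are near-identical copies, and their probes may not tell them apart. Fxyd2 (3.12 and 1.67), Atrnl1 (4.42-fold and 2.82-fold), Zfp36l1, an RNA-binding protein that destabilises messages (1.46 and 1.77), Sh3bp1 (1.61 and 1.37) and the activation marker gene Cd83 (1.68 and 1.35) were also higher, and Treml4 (-1.49 and -1.69) and Lonrf3 (-1.32 and -1.34) also lower.

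Of 14198 genes compared in both cell types, 65 were at least 2-fold higher and 103 at least 2-fold lower in both, 168 in all against 26.7 for independent lists. The majority direction depended on the scaling, with 114 higher and 71 lower when each array was centred on its median, 85 and 76 with cyclic loess, and 66 and 61 with the authors' values. The total was 75 with the normexp background correction and 381 without the filter on dim probes. Another 29 genes changed in opposite directions, against 26.9 for independent lists. The correlation of the 2 differences across 13671 genes was 0.371. Whether both cell types of a genotype came from the same mouse is not given in the sources used here, so a difference between single mice would be shared in the same way. Other probes of the changed genes had the same direction for 90.4% of probes in macrophages and 88.5% in osteoclasts, and 48.9% and 41.8% of them also passed 2-fold. Across all genes with another probe the differences of the probes had correlations of 0.554 and 0.486. For Vegfa, 3 of 4 probes were higher by 1.87 to 2.44 in both cell types, and the other was lower, at -1.38 in macrophages and -2.33 in osteoclasts.

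**Figure D4:**
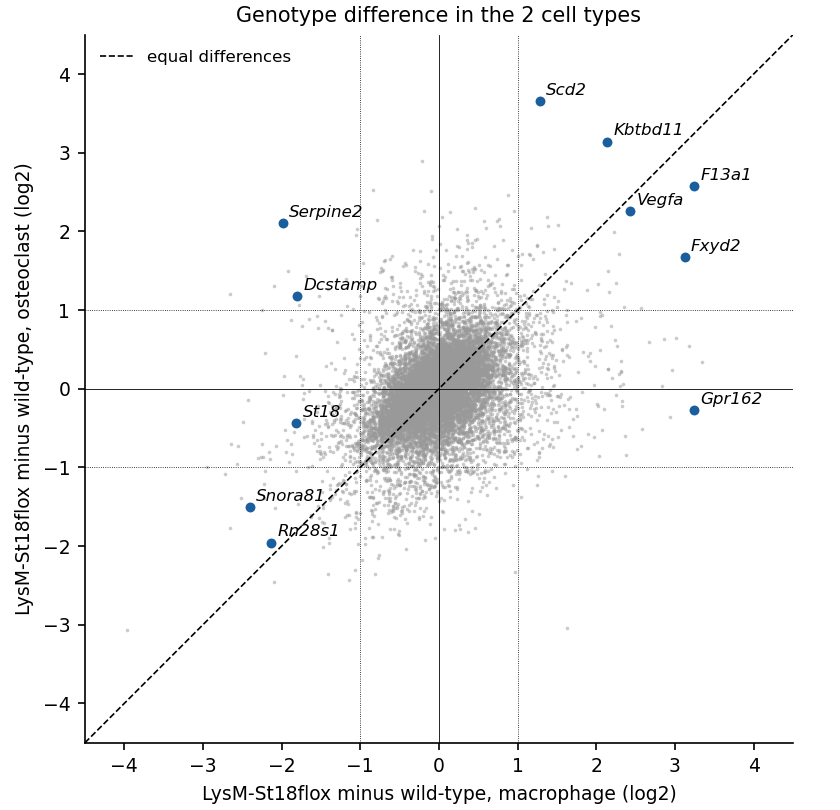
LysM-St18flox minus wild-type difference (log2) in macrophages on the horizontal axis and in osteoclasts on the vertical axis, for the 13671 genes well above background on all 4 arrays (grey points). Dotted lines mark 2-fold and the dashed line equal differences. F13a1, Vegfa and Kbtbd11 lie above 2 on both axes, while Dcstamp and Serpine2 lie below -1 in macrophages and above 1 in osteoclasts.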

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

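The tests of carried-over osteoclast RNA, hypoxia, Vegfa probes and RNAs without a poly(A) tail were chosen only after the results were seen, while those of scaling, osteoclast share, sex and neighbouring genes were chosen before.

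These 9 genes, among those named in the report or in a list, went one way in LysM-St18flox macrophages and the other way in LysM-St18flox osteoclasts, each by at least 2-fold. The difference of the osteoclast minus macrophage responses was 3.86 for Akap6, 2.10 for Cd5, 2.70 for Cyp2s1, 2.98 for Dcstamp, -2.71 for Nxpe5, 2.18 for Ocstamp, 3.01 for Pip5k1b, 3.41 for Scin and 4.09 for Serpine2. Dcstamp was at -1.81 in macrophages and 1.18 in osteoclasts and Serpine2 at -1.99 and 2.11. With 1 array per group the difference was not tested, and the 29 genes with opposite changes were about as many as the 26.9 of independent lists.

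Probes without a gene name were used in no comparison. Of 10919 such probes well above background on all arrays, 111 changed 2-fold the same way in both cell types (33 higher, 78 lower), against 18.8 for independent lists, and 17 changed in opposite ways.

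The larger response to RANKL on the LysM-St18flox arrays (slope 1.51) was weighed against 3 explanations. A compressed scale of the wild-type arrays or the scaling between arrays is argued against by the slope. It stayed at or above 1.46 under every scaling, background correction and value source run. A median shift cannot change the slope, and the authors' values are themselves quantile-normalized, so these are not separate checks. Quantile normalization gave 1.48 and cyclic loess 1.496. A larger share of osteoclasts as the whole cause would give induced genes 1 common factor. The 58 genes induced 16-fold or more instead spread 2.65 times as widely between the osteoclast arrays as non-responding genes of like signal (1.79 to 3.99 in 95% of resampled genes), with 48 higher and 10 lower. Without replicate cultures, how widely induced genes spread under a difference of share alone is unknown, so this spread does not exclude it. The share in the osteoclast culture cannot alter the macrophage arrays, however. There the 870 genes higher in osteoclasts had a median genotype difference of -0.34, and the 1212 lower ones 0.32. Over the scalings run both medians kept their sign. For these genes they argue against osteoclast share as the whole cause, but not as the cause on the osteoclast side. Osteoclast RNA in the wild-type macrophage sample, as the whole cause on the macrophage side, would need a share of 7.01% of the osteoclast signal, and 14 of the 58 genes lay under 2.94%, the lower limit of that need divided by 2. This bound was set after a first form, the median need of 7.01% against a median room of 4.75%, had decided nothing. An effect of osteoclast share on the osteoclast side, a difference between single mice or cultures, and an effect of genotype stay open as hypotheses. The last 2 of these were not tested.

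For the brightest Vegfa probe, the higher signal in LysM-St18flox is argued not to come from the scaling. Its difference stayed at or above 2.14 in both cell types under every scaling, background correction and value source run. The median over probes was not part of this check. Hypoxia of the LysM-St18flox cultures may have contributed and cannot be told apart from a genotype effect. In macrophages the glycolysis list was at percentile 11.89 and the hypoxia list without Vegfa at 86.84. In osteoclasts the hypoxia list without Vegfa was at 99.97, which goes with hypoxia, and glycolysis at 95.22, inside the random lists. Together these decide neither way. A probe that reads another transcript or another form of Vegfa also stays open, because 1 of the 4 probes was lower in both cell types and 3 were higher, and probe sequences were not used here. An effect of genotype was not tested.

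The genotype differences shared by both cell types (168 genes) were weighed against 3 explanations. A difference in sex is argued against by Xist, which differed by at most -0.58 and was present on all arrays with the Y-linked genes looked at below background. For a stretch of another strain's genome around St18, the 34 measured genes in a window around it on its chromosome were tested, in macrophages only. Their median absolute difference was at percentile 12 of random genes, with 1 changed 2-fold, so as a group they did not stand out. A median cannot register a stretch that alters only a few genes, and stretches elsewhere in the genome were not tested. Such a stretch therefore stays open. Without histone genes and structural RNAs 153 shared genes remained against 25.7 for independent lists, a ratio of 5.95, so these sets made up few of the shared genes. The sets were too small for their removal to end the pattern, and other RNAs without a poly(A) tail were not identified. The removal therefore cannot decide on uneven carry-over of such RNAs. Both sets were lower in LysM-St18flox by their medians, and carry-over in that direction would lower genes. The 65 genes higher in both cell types, against 12.3 for independent lists, all remained after the removal. They argue against such carry-over as the whole cause, while for the genes lower in both it stays open. An effect of the animal or culture shared by both cell types, and the genotype itself, may each add to the pattern and were not tested.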

How the results depend on the processing

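The count requiring all probes of a gene to go the same way, the results without histone genes and structural RNAs, and the lists without Vegfa were chosen only after the results were seen.

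Over all alternatives, gene values of named genes and list members kept within their spot spread in 9844 of 12585 cases, moved in 2739 and reversed in 2. A reversal was counted only where the main difference was at least 2-fold, so smaller values could change sign uncounted. The kept cases include 1578 of 1578 for each of the 2 filter settings (both arrays well above background, no filter on dim probes). These settings cannot change a gene value. With the median shift 781 of 1578 were kept. With the median over probes, Bcl11a in osteoclasts between genotypes was at 0.34 in place of -1.71, and Nrp2 in LysM-St18flox osteoclasts against macrophages at -0.071 in place of 1.12. Of 856 list medians, 672 stayed the same, 184 moved and 0 reversed. For lists, a reversal was counted only where the list was called apart. Other medians could change sign, as did the angiogenic list in LysM-St18flox osteoclasts against macrophages (0.17, and -0.02 with the authors' values). Of the 49 list calls, 40 were kept under every alternative run for them and 9 were lost under at least 1, among them 5 of the 9 calls between genotypes in macrophages. Calls whose medians moved by over 1.5 times under a setting that did not end them include cholesterol synthesis (0.58) and hypoxia (0.72) between genotypes in osteoclasts with a median shift, V-ATPase in wild-type osteoclasts against macrophages with quantile normalization (0.26, percentile 99.38), resorption in the same comparison with normexp (2.80), and lysosome in LysM-St18flox osteoclasts against macrophages, -0.08 with a median shift and -0.45 with cyclic loess. Others are neutrophil markers in wild-type osteoclasts against macrophages with both arrays well above background (-0.61), and between genotypes B cell and stromal markers in osteoclasts with a median shift (-0.30 and -0.20), V-ATPase in macrophages with cyclic loess (0.22), regulators and fusion genes in osteoclasts with both arrays well above background (0.37) and the median over probes (0.53), megakaryocyte markers in macrophages with normexp (0.21) and the median over probes (0.37), and the angiogenic list in macrophages with both arrays well above background (-0.53) and the authors' values (-0.42). No array could be left out, since each group had 1.

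At 1.5-fold the counts of changed genes were 4017 (osteoclast against macrophage, wild-type), 6616 (the same, LysM-St18flox), 3224 (genotypes, macrophage), 3275 (genotypes, osteoclast) and 938 (shared by both cell types), and at 3-fold 849, 1756, 248, 274 and 18. Without the filter on dim probes they were 2985 in wild-type osteoclasts against macrophages, 2093 and 2330 between genotypes in macrophages and osteoclasts, and 381 shared. These follow from the thresholds and from letting in dim probes. With normexp the counts between genotypes were 557 and 537, with 75 shared, and with the authors' values 695 in osteoclasts. An added offset, here 50 in normexp, shrinks the differences of dim probes. The authors' values were run with both arrays well above background, a filter that alone took the osteoclast count from 1132 to 906. What made up the rest of these drops was not tested. Where all probes of a gene had to go the same way, 1909, 3558, 932 and 1111 genes remained. Genes with only 1 probe measured on both arrays pass this count in any case, and 7899 of 22911 named genes had more than 1 probe.

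Between genotypes in osteoclasts, 49.1% of changed genes were higher. The share was 75.9% with a median shift, 67.6% with cyclic loess, 62.1% with quantile normalization, 62.2% with the authors' values and 59.2% with normexp. The median of all genes in this comparison was -0.01 and became 0.24 with the median shift. In LysM-St18flox osteoclasts against macrophages it became 0.16, and the share higher went from 47.2% to 59.2%. Of the shared genes 65 were higher and 103 lower, and with the median shift 114 and 71. Directions of modest changes between genotypes in osteoclasts are therefore relative to the scaling.

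The slope between the responses was 1.46 with the authors' values, 1.48 with quantile normalization, 1.496 with cyclic loess, 1.54 with normexp and 1.51 without histone genes and structural RNAs, each above 1. The St18 difference between macrophages was -1.53 with normexp and -0.55 with the median over probes, which mixes in the dim probe. The cause of the other shifts was not tested. Dim probes limit the comparisons: 13671 of 22903 genes were well above background on all arrays.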

Other observations

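The sets in this part were chosen only after the results were seen, and no test of their cause was made.

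Structural noncoding RNAs (26 measured) had a median difference between genotypes of -0.76 in macrophages, with 7 lower by 2-fold, and -0.49 in osteoclasts, with 4 lower. Over the scalings run these ran from -0.79 to -0.72 and from -0.49 to -0.24. In osteoclasts against macrophages they were at 0.60 in the wild type and 0.95 in LysM-St18flox. Histone genes (64 measured) had medians of -0.57 and -0.46 between genotypes, with 12 lower in each cell type and H2bc21 higher in osteoclasts (1.51), and ran from -0.57 to -0.29 and from -0.46 to -0.23 over the scalings. In osteoclasts against macrophages they were at 0.01 and 0.11, within the random lists.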
